A study of Mus musculus with 14 samples.

How the data were processed

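Total RNA of sorted mouse hair follicle stem cells was sequenced as single-end reads, per the labels' protocols. Back skin was digested with trypsin, the epidermal cells were collected, and cells positive for CD34 and for a marker written as CD45f, and negative for Ly-6A/E, were isolated by flow sorting, per the labels' protocols. Reads were assigned to transcripts with kallisto 0.46.2, per the labels' protocols. The submitters' processing notes also name the mouse build mm10 and DESeq2, without a version. The transcript annotation behind the quantification was not given in the sources used here.

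The authors deposited 1 table per library, which lists 118489 transcripts with an estimated count, a TPM value and an effective length, per the file headers. Neither the estimated counts nor the TPM values were changed before they were deposited in any way that the file headers record. Of these transcripts, 116816 were matched by identifier to a gene of the GENCODE annotation of the GRCm38 (mm10) assembly and 1673 were not. The unmatched transcripts held between 1.19% and 2.59% of the estimated counts of a library and were left out. Estimated counts were summed over the transcripts of each gene and rounded to whole numbers. The kallisto tool shares reads between near-identical transcripts by a statistical model, so values of multi-copy genes are uncertain, among them the clustered histone genes, Rpl26 with its pseudogenes and the receptor gene families. The labels do not state a strand setting, so a gene and an antisense partner that overlaps it could not be told apart.

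The 14 libraries were grouped by the age and genotype in their titles. A 6-digit code in the deposited data was read as a processing date, with 2 dates at each age and both genotypes on each date. Whether the code marks the sort, the library or the sequencing was not given in the sources used here. The comparisons, covariates, gene lists, other settings to try and the rule for named genes were fixed before the data were examined. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter by group and robust quasi-likelihood tests over all 14 libraries. The filter kept 24592 of 34049 genes with any count. The comparisons of labelled Irx5KO with labelled WT and their difference between ages had the date within age as a covariate. The comparisons of P20 with P18 had none, because each age had its own dates, so age and date could not be separated. Differences within a date came from a fit with 1 coefficient per date and genotype. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene passed at an adjusted p under 0.05. Fold changes are log2 values with a standard error (SE). For edgeR the SE was derived as the size of the fold change over the square root of the F statistic of its test. It is therefore approximate, above all for fold changes near 0. CPM values, counts scaled to a common library total, were computed from the summed counts with TMM library sizes unless stated otherwise.

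The text always names Irx5, Irx3, Irx6, Fgf18, Brca1, Cd34, Nfatc1, Lgr5, Gli1, Mki67 and Cdkn1a. In each comparison it may also name the 8 largest rises and the 8 largest falls among the genes that passed with a mean log2 CPM of at least 1. In a comparison of genotypes, such a gene also had to have the same sign on both dates of that age. Where none passed in a direction, the 4 with the smallest p may be named as not passing. Up to 4 members with the smallest p may be named for a gene list, and up to 3 of the most abundant for markers of other cells. Gene models with provisional names and pseudogenes were counted but not named. Genes named outside this rule are said to have been chosen after their values were seen. For differences within a date, the same sign on the other date was not asked for.

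A set of 62 gene lists with 998 symbols covered stem cell compartments, signalling, DNA repair, the cell cycle, metabolism, stress, immunity and other cell types of skin. Of these symbols, 8 matched no gene. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. Their p-values were adjusted over the lists of a comparison. Counts of members called are over all genes tested, and beside them are counts adjusted over the list alone. The targeted gene was compared between the labelled genotypes with a two-sided exact permutation test of CPM.

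The settings fixed beforehand were the median-ratio size factors of DESeq2 used in edgeR (RLE), no expression filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom with sample quality weights, and transcript length offsets. They also included no date term, replicate number as a block, fits of each age or of the compared groups alone, date as a random effect, and leaving out each library in turn. Chosen after seeing the data were tests over well expressed genes (at least 5 CPM in at least 4 libraries), and fits without the P20 libraries numbered 3 and 4 or without the 3 libraries richest in receptor gene counts. At P18, the deviations from the group means of libraries with the same replicate number had Pearson correlations across genes of 0.361, 0.129 and 0.283. All are above 0.1, so the numbers were tried as a pairing of the P18 libraries, although the labels name no shared litter or day. The libraries numbered 2, at 0.129, carried different dates. They also differed in the Y-linked gene Ddx3y, at 0.54 CPM in WT 2 and 112 CPM in Irx5KO 2 at raw library sizes. The numbers therefore do not mark a shared date throughout, and the main P18 test did not use them. With the number as a block, 0 genes passed at P18 and 2354 had an unadjusted p under 0.05.

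The edgeR steps were tested on simulated data with the real genes, means and library sizes, in which 50 genes were changed at each of 4 fold sizes. Every case took its spread from the fit with the date covariate, which is not the fit used for age or within a date. Only genes with a mean log2 CPM above 1 were changed, and no date or receptor gene difference was simulated. The shares below therefore describe the simulated data and may differ in the real tests. For genotype at P18, 44% of genes changed 4-fold and 60% of those changed 8-fold were recovered. For genotype at P20 these shares were 52% and 80%, for the difference between ages 4% and 42%, for age in WT 36% and 72%, and for age in Irx5KO 48% and 62%. Within the P20 libraries 1 and 2, with 2 against 2 libraries, they were 22% and 48%. Over all 4 fold sizes, the simulated test within these libraries made 71 true and 11 false calls. True and false calls were 95 and 8 for genotype at P18 and 110 and 9 at P20. They were 55 and 5 for the difference between ages, 95 and 9 for age in WT, and 98 and 6 for age in Irx5KO. In each of these comparisons the false share of the calls was above the adjusted p threshold. Totals per library and intervals of count ratios describe counting error only. Fold changes against a group with 0 counts are lower bounds against a floor of 3 counts over the group. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.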

Results

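Gene expression was measured by bulk RNA sequencing in mouse hair follicle stem cells, the CD34-positive bulge cells that are largely quiescent between hair growth phases and divide when a new phase starts. Cells were taken at postnatal day 18 (P18) and postnatal day 20 (P20). The title of the series names a role of the transcription factor IRX5 in DNA damage repair and in the activation of these cells, and the design compares Irx5 knockout (Irx5KO) with wild type (WT) at both ages. There were 3 libraries labelled Irx5KO and 3 labelled WT at P18, and 4 of each at P20. Total estimated counts ranged from 13618367 in the library labelled P20 Irx5KO 3 to 70083873 in that labelled P18 Irx5KO 3. At P18 the totals were 36671532, 52863003 and 70083873 for Irx5KO 1 to 3 and 34483316, 20554772 and 46604801 for WT 1 to 3. At P20 they were 39056352, 35871129, 13618367 and 18123209 for Irx5KO 1 to 4 and 41372580, 23690517, 32515327 and 16922104 for WT 1 to 4. Every pair of replicates differed by more than sampling noise (chi-square per degree of freedom 72.4 to 861). The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. The earlier P18 date held Irx5KO 1, WT 1 and WT 2, and the later one Irx5KO 2, Irx5KO 3 and WT 3. At P20 the libraries numbered 3 and 4 of both genotypes carried the earlier date and those numbered 1 and 2 the later one. The deposited data of the library labelled P18 WT 3, the single WT library of its date, also carry the word het, while its title says WT, and the title was used. The Y-linked gene Ddx3y, chosen after its values were seen, had 58.5 to 129 CPM at raw library sizes in the later P18 libraries, in both P20 libraries numbered 2 and in all 4 numbered 3 and 4. It had 0.123 to 0.589 CPM in the earlier P18 libraries and in both P20 libraries numbered 1. By Ddx3y, date and sex therefore cannot be told apart at P18, and all P20 libraries of the earlier date were male. Summed over the P18 libraries, Ddx3y had 4444 counts in WT and 14811 in Irx5KO, and Eif2s3y 2161 and 4972. The Y-linked Kdm5d (11919 and 7045) and Uty (14302 and 9537) ran the other way. These genes were also chosen after their values were seen, and sexes in the text are those read from Ddx3y.

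Irx5 (ENSMUSG00000031737.11, chromosome 8, 92357625 to 92376286, plus strand, mm10) encodes an Iroquois homeobox transcription factor and is the targeted gene. Its transcripts were present in every library, with 607 to 6199 counts. At P18, Irx5 was at 53.3, 72.5 and 81.9 CPM in the libraries labelled Irx5KO and at 80.0, 63.9 and 136 CPM in those labelled WT. The means were 69.2 ± 14.6 and 93.4 ± 38.1 CPM (SD, n = 3 each; exact permutation test, p = 0.5, where 0.1 is the smallest p possible). Under 3 other scalings every P18 library labelled Irx5KO lay below every one labelled WT (exact permutation test, p = 0.1 each). The means were 62.8 and 116 CPM at raw library sizes, 31.4 and 55.7 TPM, and 65.1 and 110 CPM with TMM over well expressed genes, a scaling chosen after the data were seen. Without the library labelled P18 WT 3 the log2 ratio of the TMM means was -0.06, against -0.43 with it. At P20, the libraries labelled Irx5KO 1 and 2 had 31.5 and 18.7 CPM, below the 126 and 73.8 CPM of those labelled WT 1 and 2. The libraries labelled Irx5KO 3 and 4, at 195 and 182 CPM, were above every other library, and those labelled WT 3 and 4 had 39.0 and 43.0 CPM. The P20 means were therefore 107 ± 94.6 CPM for Irx5KO and 70.5 ± 40.3 CPM for WT (SD, n = 4 each; exact permutation test, p = 0.486, with 0.0286 the smallest p possible). Irx5 thus went against the genotype labels in the P20 libraries numbered 3 and 4. All genotypes below are those of the labels, and every direction between genotypes at P20 rests on them. The part of the gene removed in the allele was not given in the sources used here, and counts over the whole gene can miss the loss of a part.

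**Figure D1:**
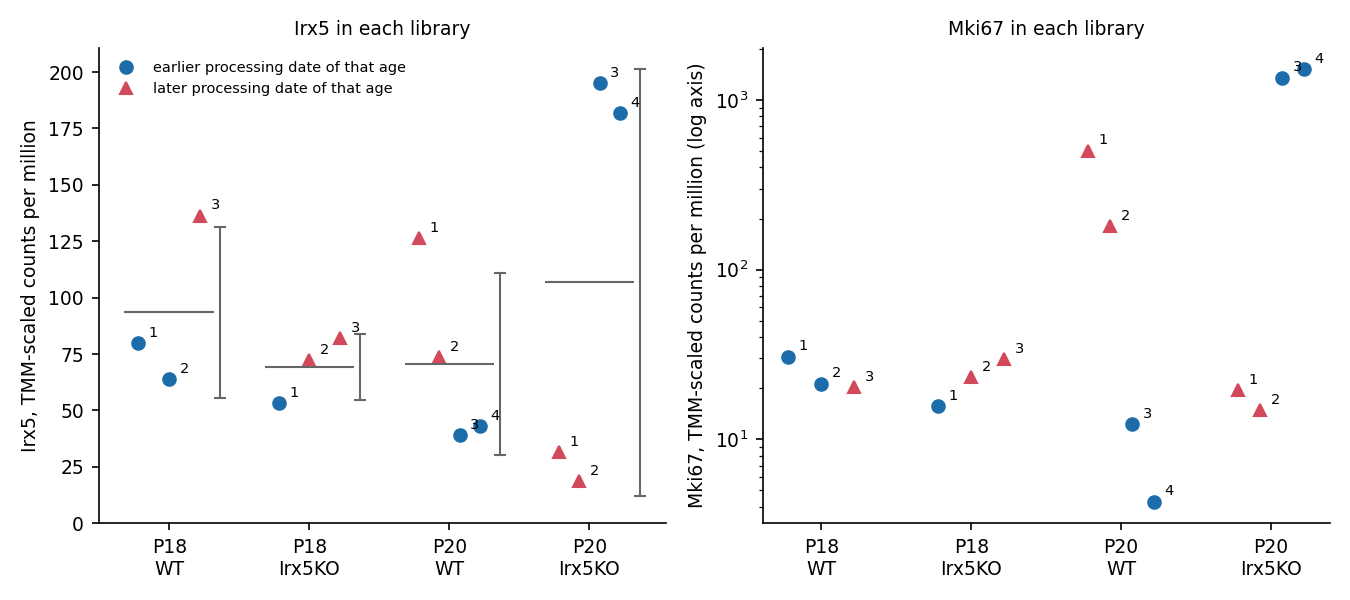
Irx5 (left) and the proliferation marker Mki67 (right, log axis) in TMM-scaled CPM in each of the 14 libraries, by labelled group, with the replicate number beside each point, shapes for the processing date and, for Irx5, the mean and SD. Irx5 and Mki67 were both high in the libraries labelled P20 Irx5KO 3 and 4 (195 and 182 CPM of Irx5, 1352 and 1515 CPM of Mki67) and both low in those labelled P20 WT 3 and 4.

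At P18 the libraries labelled Irx5KO and WT were compared in stem cells before the hair growth phase. The stem cell markers Cd34, Lgr5 and Nfatc1 had log2 differences (Irx5KO minus WT) of -0.05 ± 0.47, 0.41 ± 0.45 and 0.87 ± 0.46 (SE, 3 against 3 libraries), and none passed the test. Fgf18, a growth factor that holds bulge cells in quiescence, was at -0.31 ± 1.29, Brca1, which acts in homologous recombination, at -0.24 ± 2.34 and Mki67 at -0.17 ± 2.26. These SE rest on a spread estimated over all 14 libraries, so differences among the P20 libraries enter them. The P18 libraries themselves had 15.6 to 30.7 CPM of Mki67. The smallest p-values belonged to Igfbp7 (1.48 ± 0.40), Zc3h12c (1.49 ± 0.42), Gcc1 (1.51 ± 0.43) and Il11ra2 (4.69 ± 1.25) on the higher side. On the lower side they belonged to Speer4e (-5.05 ± 1.52), Olfr251 (-2.73 ± 0.95), Atp5g2 (-1.72 ± 0.61) and Hmcn2 (-3.51 ± 1.26). The edgeR test called 0 of 24592 genes, with 1195 at an unadjusted p under 0.05 and a smallest adjusted p of 0.82. DESeq2 called 19 and voom with sample quality weights 11. Irx6, the third gene of the Irx3 and Irx5 cluster, was at -4.42 ± 2.55, with 274 counts in the libraries labelled WT and 14 in those labelled Irx5KO. Of the 274, 241 lay in P18 WT 1 and 2, and in all 14 libraries Irx6 was below the level of receptor gene counts over its length. Irx5 was at -0.63 ± 0.79, Irx3, the neighbouring Iroquois gene, at 0.43 ± 0.38, Gli1 at -0.18 ± 0.72 and Cdkn1a, the gene of the cell cycle inhibitor p21, at 1.24 ± 0.76.

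Counts of olfactory and vomeronasal receptor genes differed between the P18 libraries. These 1973 genes took 1.80% and 5.45% of the counts in the libraries labelled P18 WT 1 and 2 and 2.41% in that labelled P20 WT 2, against 0.102% to 0.611% in the other 11. TMM scaling over all genes kept gave these 3 libraries factors of 1.27, 1.76 and 1.39, and the others 0.802 to 1.01. As a result the median log2 difference of genes with at least 8 CPM was 0.35 at P18, 0.42 for age in WT and 0.71 on the earlier P18 date. For the difference of the genotype effect between ages it was -0.37. It was -0.03 at P20, 0.00 for age in Irx5KO, 0.04 within P20 libraries 1 and 2 and -0.11 within libraries 3 and 4. Gene groups at P18 and for age in WT are therefore given over the 12624 well expressed genes with the scaling recomputed on them, a set chosen after the data were seen.

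Among these, response genes leaned higher in the libraries labelled P18 Irx5KO as groups, although no member passed. Of the 28 immediate early and dissociation response genes, 27 were positive, with a median of 0.63 (camera adjusted p = 5.7e-10, adjusted p = 0.54 with an estimated correlation). In the test over all genes the transcription factors Egr3 and Egr2 were at 1.66 ± 0.56 and 1.14 ± 0.44. All 17 FGF and ERK response genes were positive (median 0.58, adjusted p = 2.6e-07, adjusted p = 0.39 with an estimated correlation), among them the ERK phosphatase gene Dusp6 at 1.41 ± 0.49 and the AP-1 gene Fosl1 at 1.66 ± 0.60. All 13 NF-kB and cytokine genes were positive (median 0.88, adjusted p = 2.1e-07, adjusted p = 0.39 with an estimated correlation), with Birc3 at 1.18 ± 0.42 and the adhesion molecule gene Icam1 at 1.29 ± 0.47. Of 37 G2/M and mitosis genes, 35 were negative (median -0.98, adjusted p = 0.0062, adjusted p = 0.81 with an estimated correlation). In each of these 4 lists 0 members passed, also when adjusted over the list alone. Over all genes the immediate early median was 1.66 on the earlier date and 0.18 on the later one, and the G2/M median -1.09 and 0.12. The NF-kB and cytokine median was 1.23 and 1.07 on these dates, and the FGF and ERK response median 1.19 and 0.61. These medians over all genes, and those of other cells below, are to be set against the median of genes with at least 8 CPM. It was 0.71 on the earlier date and 0.04 on the later one. The infundibulum and junctional zone median was 0.65 and 0.87 on these dates, above that level only on the later one. The T cell median was -2.27 and 0.49, and the hair shaft keratin median -2.46 and -0.20. On the earlier date the mast cell, skeletal muscle and erythroid medians were also low, at -1.72, -2.65 and -2.19. Those of suprabasal epidermis and sebaceous gland were 0.27 and 0.29 there. The earlier date set 1 library labelled Irx5KO against the receptor-rich P18 WT 1 and 2. Camera called 28 of 62 lists over all genes and 16 of 57 over the well expressed ones, and 0 with an estimated correlation in either. The 28 became 8 without the library labelled P18 Irx5KO 1.

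At P20 the same comparison was made at the age when some of these libraries held many mitotic transcripts. Pooled over both dates, Mki67 was at 1.53 ± 6.25 and Brca1 at 1.33 ± 4.84 (log2, Irx5KO minus WT, SE, 4 against 4 libraries), where the SE exceeds the estimate because the dates went opposite ways. Fgf18 was at -0.99 ± 1.74, Gli1, a target of Hedgehog signalling, at -0.01 ± 0.76, Cd34 at -0.36 ± 0.42 and Irx5 at 0.10 ± 0.84. Lgr5, Nfatc1, Cdkn1a, Irx3 and Irx6 were at -0.34 ± 0.39, -0.10 ± 0.39, -0.32 ± 0.74, 0.04 ± 0.32 and -0.15 ± 2.02. The smallest p-values were those of the matrix gene Fn1 (1.16 ± 0.34), Jpt1 (1.43 ± 0.42), Plekhb1 (2.06 ± 0.61) and the necroptosis kinase gene Ripk3 (1.28 ± 0.40). On the lower side they were those of Zfp867 (-1.73 ± 0.44), Adamts4 (-4.52 ± 1.18), Vmn1r226 (-2.85 ± 0.81) and the sodium channel gene Scn8a (-1.90 ± 0.54). With edgeR 0 genes passed, with 1004 at an unadjusted p under 0.05 and no adjusted p below 0.95. DESeq2 called 85 and voom with sample quality weights 135. All 39 G2/M and mitosis genes were positive (camera adjusted p = 1.8e-11, adjusted p = 0.82 with an estimated correlation). Of 40 G1/S and DNA replication genes 38 were (adjusted p = 3.6e-13, adjusted p = 0.74 with an estimated correlation), with Cdt1 at 0.94 ± 0.36 and E2f1 at 1.35 ± 0.52. Of 30 homologous recombination genes, 18 were positive (adjusted p = 0.019, adjusted p = 0.82 with an estimated correlation), and of 11 endothelial markers, 2 were (adjusted p = 9.0e-04, adjusted p = 0.74 with an estimated correlation). Of 15 granular and cornified epidermis markers 12 were positive (adjusted p = 7.3e-06, adjusted p = 0.74 with an estimated correlation). In these 5 lists 0 members passed, also when adjusted over the list alone.

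The pooled P20 value joined dates with opposite differences. Without the libraries numbered 3 and 4, an alternative chosen after seeing the data, 119 genes passed at P20, 24 higher and 95 lower in the libraries labelled Irx5KO.

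Within the P20 libraries 1 and 2, the libraries labelled Irx5KO had far fewer transcripts of cell division genes than those labelled WT. Here Irx5 was lower in the libraries labelled Irx5KO (-2.00 ± 0.42, edgeR adjusted p = 0.028, 2 against 2 libraries). Mki67 was lower by -4.32 ± 0.60 (adjusted p = 7.9e-04), Top2a, which untangles DNA in dividing cells, by -4.62 ± 0.53 (adjusted p = 1.2e-04) and the kinetochore gene Kntc1 by -5.33 ± 0.56 (adjusted p = 5.7e-05). Brca1 was at -3.97 ± 0.59 (adjusted p = 0.0016) and Gli1 at -1.91 ± 0.41 (adjusted p = 0.039). On the higher side were the cell cycle inhibitor gene Cdkn1c (3.27 ± 0.44, adjusted p = 6.9e-04), Angptl7, a bulge marker (2.95 ± 0.58, adjusted p = 0.019), and Rpl26 (4.44 ± 0.73, adjusted p = 0.0092), which shares reads with its pseudogenes. Also among the largest rises were Rbpjl (2.68 ± 0.58), Ccl7 (2.62 ± 0.58), Dlk1 (2.49 ± 0.46), Rnf227 (2.41 ± 0.43) and Dab2 (2.19 ± 0.40). Fgf18 (1.99 ± 0.67, adjusted p = 0.56), Cdkn1a (1.38 ± 0.56, adjusted p = 0.88), Cd34 (0.47 ± 0.46), Lgr5 (0.12 ± 0.49), Nfatc1 (0.07 ± 0.52), Irx3 (0.22 ± 0.43) and Irx6 (-0.16 ± 2.15) did not pass.

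In all, 116 genes passed within these libraries, 15 higher and 101 lower in those labelled Irx5KO, and 1234 had an unadjusted p under 0.05. Of the 39 G2/M and mitosis genes, 17 fell, 0 rose and 22 did not pass, and 33 fell when adjusted over the list alone (camera adjusted p = 7.8e-80, adjusted p = 0.048 with an estimated correlation). The spindle checkpoint gene Bub1b was at -4.02 ± 0.53, Cenpf at -3.72 ± 0.52, and Bub1 had 1 count in the libraries labelled Irx5KO against 535, a ratio of 535 after scaling (95% interval 95.6 to 21170). Among the 40 G1/S and DNA replication genes, 7 fell, 17 when adjusted over the list alone (adjusted p = 4.9e-19, adjusted p = 0.048 with an estimated correlation), among them the helicase genes Mcm2 (-2.78 ± 0.38) and Mcm3 (-2.56 ± 0.41). Of 30 homologous recombination genes, 3 fell, 4 when adjusted over the list alone (adjusted p = 8.4e-08, adjusted p = 0.049 with an estimated correlation). They were Brca1, its partner Bard1 (-2.64 ± 0.59, adjusted p = 0.046) and Rad54b (-4.49 ± 0.78, adjusted p = 0.0063). Whether these genes changed apart from cell division was not tested. Of 16 replication-dependent histone genes, 7 fell, 13 when adjusted over the list alone (adjusted p = 4.5e-32, adjusted p = 0.069 with an estimated correlation), and reads of this family can be shared between copies. In the Fanconi anaemia pathway, 2 of 18 members fell, with Fancd2 at -3.69 ± 0.71 (adjusted p = 0.015), and the list itself was not called.

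Within these libraries the 21 bulge stem cell markers held 1 gene that rose, Angptl7, and 1 that fell, the integrin gene Itgb6 (-2.23 ± 0.42, adjusted p = 0.011). These counts were also 1 and 1 when adjusted over the list alone (adjusted p = 0.0019, adjusted p = 0.64 with an estimated correlation). Of 21 quiescence factors 1 rose, Cdkn1c, while over the list alone 2 rose and 1 fell (adjusted p = 1.5e-04, adjusted p = 0.64 with an estimated correlation). Markers of granular and cornified epidermis, another cell type of the tissue, were positive in 15 of 15 with none passing (adjusted p = 0.0020, adjusted p = 0.64 with an estimated correlation). The count of 116 was 42, 15 and 43 without the libraries labelled P20 Irx5KO 1, Irx5KO 2 and WT 1, and 393, 183 and 176 without those labelled P18 WT 1, 2 and 3, which share the estimate of spread. DESeq2 called 463 genes and voom with sample quality weights 11, and 209 passed without the 3 libraries richest in receptor genes.

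Within the P20 libraries 3 and 4 the difference ran the other way, and cell division genes were far higher in the libraries labelled Irx5KO. In this pair of replicates Irx5 itself was higher in the libraries labelled Irx5KO (2.20 ± 0.42, edgeR adjusted p = 0.0030, 2 against 2 libraries), against the label. Mki67 was at 7.42 ± 0.69 (adjusted p = 1.7e-06), Brca1 at 6.98 ± 0.70 (adjusted p = 3.2e-06), Cenpf at 8.00 ± 0.64, Bub1b at 7.66 ± 0.64 and Depdc1a at 8.61 ± 1.93 (adjusted p = 0.041). Fgf18 was at -4.04 ± 0.73 (adjusted p = 0.0051), Cdkn1c at -2.99 ± 0.44 (adjusted p = 2.6e-04), Angptl7 at -4.10 ± 0.62 (adjusted p = 3.0e-04) and Gli1 at 1.90 ± 0.41 (adjusted p = 0.0096). Cdkn1a (-2.03 ± 0.57, adjusted p = 0.051), Cd34 (-1.20 ± 0.46, adjusted p = 0.19), Lgr5 (-0.79 ± 0.49), Nfatc1 (-0.28 ± 0.52) and Irx3 (-0.14 ± 0.43) did not pass, and Irx6 had 0 counts.

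Here 1028 genes passed, 388 higher and 640 lower in the libraries labelled Irx5KO, and 3819 had an unadjusted p under 0.05. Some of the largest changes were against 0 counts. The histone gene Hist1h2ap was at least 3369-fold and the mitotic kinase gene Pbk at least 557-fold higher in the libraries labelled Irx5KO. Adamtsl3 was at least 108-fold, the desmosomal gene Dsg4 at least 83.6-fold and Rab17 at least 79.5-fold lower there. The libraries labelled Irx5KO 3 and 4 were also among the shallowest, with 15459 and 15184 genes detected against 18383 to 31655 in the others. Of the 39 G2/M and mitosis genes, 36 rose, 0 fell and 3 did not pass, and 39 rose when adjusted over the list alone (camera adjusted p = 2.1e-156, adjusted p = 0.0036 with an estimated correlation). Of 40 G1/S and DNA replication genes, 25 rose, 33 when adjusted over the list alone (adjusted p = 1.1e-58, adjusted p = 0.0036 with an estimated correlation), with Uhrf1 at 5.18 ± 0.46 and Mcm5 at 5.02 ± 0.45.

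Lists of cell handling and stress also had opposite signs on the 2 dates. Of 28 immediate early and dissociation response genes, 26 were negative within the libraries 3 and 4 (median -1.07) and 2 fell, also 2 when adjusted over the list alone (camera adjusted p = 5.1e-06, adjusted p = 0.87 with an estimated correlation). Within the libraries 1 and 2, 26 were positive (median 0.64) and 0 passed, with 3 higher when adjusted over the list alone (adjusted p = 3.8e-12, adjusted p = 0.64 with an estimated correlation). Of 15 heat shock and chaperone genes, 12 were negative within the libraries 3 and 4 (median -0.72) and 1 fell, 3 when adjusted over the list alone (adjusted p = 0.045, adjusted p = 0.97 with an estimated correlation). Within the libraries 1 and 2, 11 were positive (median 0.75) and 0 passed, also when adjusted over the list alone (adjusted p = 8.3e-06, adjusted p = 0.64 with an estimated correlation).

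Within the P20 libraries 3 and 4, members of some DNA repair lists rose. Of the repair lists in this paragraph, only homologous recombination was called with an estimated correlation. Non-homologous end joining and nucleotide excision repair had medians of -0.32 and -0.11 with 0 of 13 and 0 of 23 genes passing. The lists were not tested against each other. Some repair lists share members with the G1/S list, such as Rpa2 in homologous recombination and Uhrf1 in the Fanconi anaemia pathway. The libraries labelled Irx5KO 3 and 4 had 1352 and 1515 CPM of Mki67, against 12.3 and 4.30 CPM in those labelled WT 3 and 4. Whether repair genes changed apart from cell division was not tested. Of 30 homologous recombination genes, 11 rose, 12 when adjusted over the list alone (adjusted p = 7.8e-14, adjusted p = 0.012 with an estimated correlation). Among them were the recombination helicase gene Rad54l (5.34 ± 0.64), Brip1 (3.45 ± 0.51) and Bard1 (4.11 ± 0.63). In the Fanconi anaemia pathway 4 of 18 rose, 5 when adjusted over the list alone (adjusted p = 1.2e-07, adjusted p = 0.11 with an estimated correlation), with Fancd2 at 4.96 ± 0.76. Of 17 DNA damage checkpoint genes 4 rose, 5 when adjusted over the list alone (adjusted p = 2.3e-05, adjusted p = 0.16 with an estimated correlation). The checkpoint kinase gene Chek1 was at 3.57 ± 0.84 (adjusted p = 0.017) and Timeless at 3.53 ± 0.47. Hedgehog target genes held 3 of 11 that rose, 4 when adjusted over the list alone (adjusted p = 0.0033, adjusted p = 0.48 with an estimated correlation). These were Gli1, Hhip (2.84 ± 0.59) and the Hedgehog receptor gene Ptch1 (2.04 ± 0.45, adjusted p = 0.011). Of 22 cholesterol synthesis genes 3 rose, 7 when adjusted over the list alone (adjusted p = 8.8e-11, adjusted p = 0.46 with an estimated correlation), with Idi1 at 2.54 ± 0.50 and Cyp51 at 2.41 ± 0.51. Of 19 circadian clock genes 3 fell, 5 when adjusted over the list alone (adjusted p = 0.0045, adjusted p = 0.71 with an estimated correlation), among them Tef (-2.51 ± 0.43). Granular and cornified epidermis markers were positive in 10 of 15 (median 0.95, 0 passing), and the list was not called (camera adjusted p = 0.16). Endothelial markers, a sign of other cells in the sort, had 0 of 11 positive and 2 that fell, also 2 when adjusted over the list alone (adjusted p = 0.029, adjusted p = 0.71 with an estimated correlation). The count of 1028 was 415 and 594 without the libraries labelled P20 WT 3 and WT 4 and 1845 without that labelled P18 WT 1. Over the well expressed genes, with the scaling recomputed, 1205 passed, 580 higher and 625 lower. DESeq2 called 2647 genes, voom with sample quality weights 1937, and 1863 passed without the 3 libraries richest in receptor genes.

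The 2 dates of P20 were compared directly by the interaction of date and labelled genotype. For 965 genes the labelled genotype difference differed between the dates, 462 more positive and 503 more negative in the libraries 3 and 4. Over the well expressed genes there were 1392, 720 more positive and 672 more negative. The date difference was 4.20 ± 0.59 for Irx5 (adjusted p = 1.0e-04), 11.73 ± 0.91 for Mki67 (adjusted p = 7.6e-08), and 3.80 ± 0.59 for Gli1 (adjusted p = 3.0e-04). It was -6.03 ± 0.99 for Fgf18 (adjusted p = 0.0019) and -3.40 ± 0.80 for Cdkn1a (adjusted p = 0.017). Brca1 was at 10.94 ± 0.91 (adjusted p = 1.7e-07), while Cd34 (-1.66 ± 0.65), Lgr5 (-0.91 ± 0.69), Nfatc1 (-0.35 ± 0.74) and Irx3 (-0.35 ± 0.61) did not pass, and Irx6 had no value for want of counts. Of 39 G2/M and mitosis genes, 36 differed, 39 when adjusted over the list alone (camera adjusted p = 2.2e-185, adjusted p = 0.0042 with an estimated correlation). A total of 103 genes passed on both dates, and all 103 had opposite signs. Of these, 92 were lower and then higher, where independent lists would share 1.59, and 11 were higher and then lower, where 0.39 would be shared. Across 10356 genes with a mean log2 CPM of at least 3, the log2 differences of the dates had a Pearson r of -0.489 and a Spearman rho of -0.445, across genes, which are not independent replicates, and 33.2% had the same sign. The count of 965 was 544, 510 and 1742 without the libraries labelled P20 Irx5KO 2, P20 WT 3 and P18 WT 1, and 1516 without the 3 libraries richest in receptor genes.

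**Figure D2:**
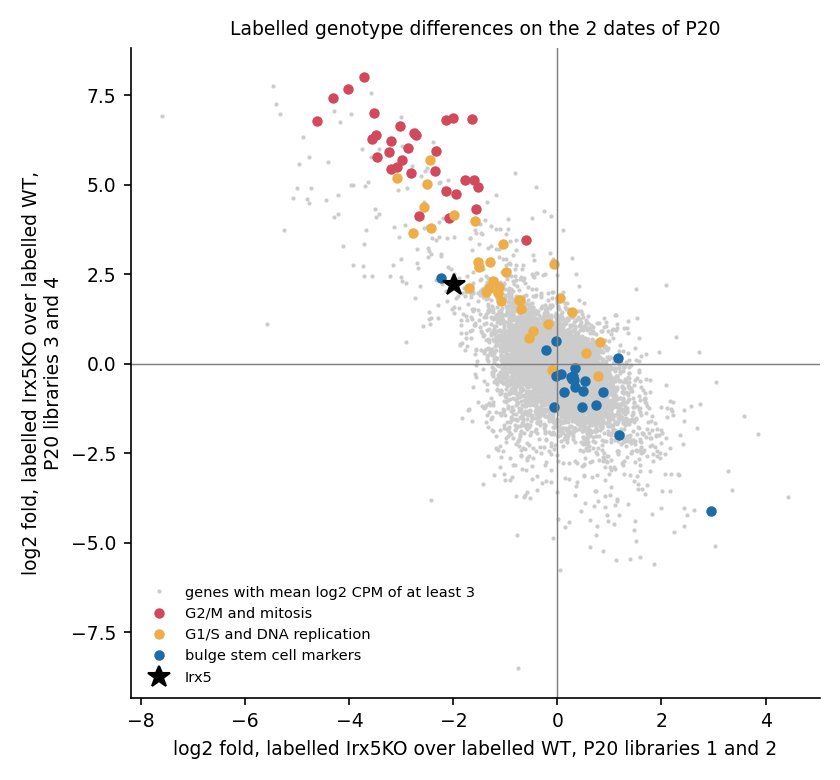
Log2 difference of labelled Irx5KO over labelled WT in the P20 libraries 1 and 2 (horizontal axis) and 3 and 4 (vertical axis), 1 point per gene with a mean log2 CPM of at least 3 and more than 3 counts on every side. The mitosis and replication genes and Irx5 lie at the upper left, lower in libraries 1 and 2 (Irx5 -2.00) and higher in 3 and 4 (Irx5 2.20).

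**Figure D3:**
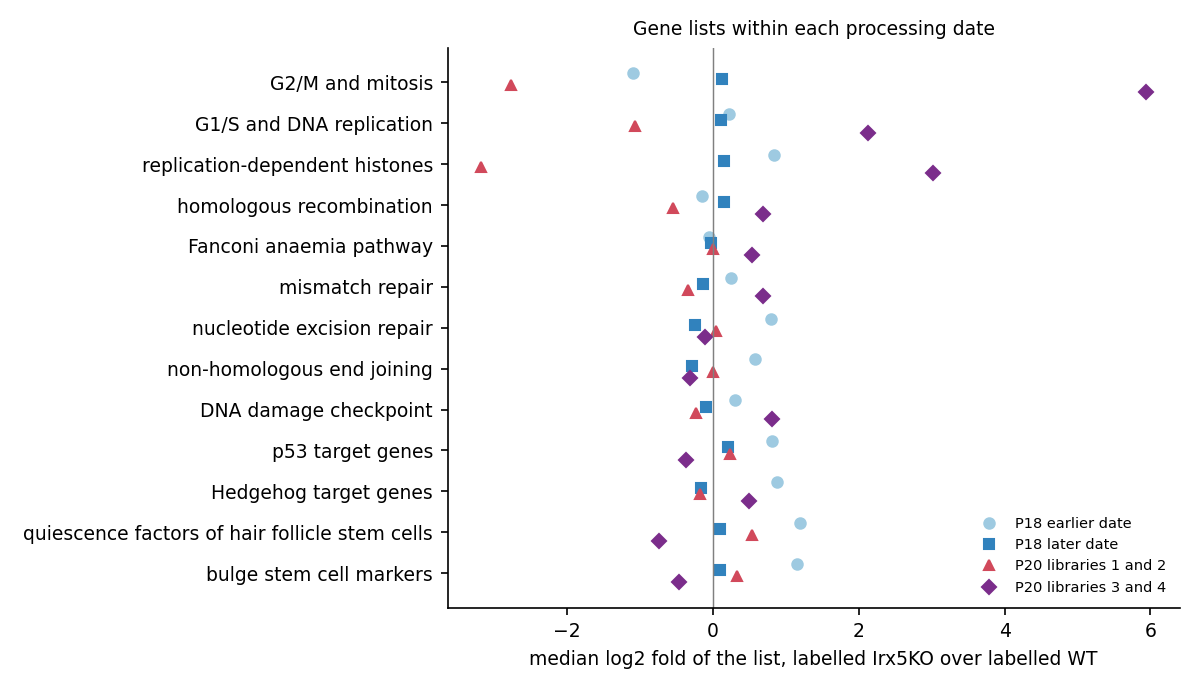
Median log2 difference of labelled Irx5KO over labelled WT for 13 gene lists, 1 point per list and processing date, with genes at 0 counts on a side set at their bound. The G2/M list lies at -2.77 in the P20 libraries 1 and 2 and at 5.95 in 3 and 4, and points of the earlier P18 date are to be set against the median of 0.71 of genes with at least 8 CPM.

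The difference of the labelled genotype effect between P20 and P18 was tested to ask whether it changes between the ages. Irx5 was at 0.73 ± 1.15, Mki67 at 1.70 ± 6.66, Brca1 at 1.57 ± 5.39 and Cdkn1a at -1.57 ± 1.06 (log2, P20 minus P18, SE, all 14 libraries). Fgf18, Cd34, Nfatc1, Lgr5, Gli1, Irx3 and Irx6 were at -0.67 ± 2.18, -0.32 ± 0.63, -0.97 ± 0.60, -0.74 ± 0.59, 0.17 ± 1.04, -0.39 ± 0.49 and 4.27 ± 3.45. The smallest p-values belonged to the matrix gene Fmod (2.87 ± 0.91), the kinesin gene Kif24 (1.41 ± 0.48), the kinetochore gene Ska3 (2.37 ± 0.89) and Plekhb1 (2.37 ± 0.92). Negative were Rnf146 (-1.66 ± 0.50), Il11ra2 (-4.98 ± 1.5), Zfp867 (-2.20 ± 0.67) and Papln (-1.77 ± 0.56). In the edgeR test 0 genes passed, with 448 at an unadjusted p under 0.05. DESeq2 called 13 and voom with sample quality weights 0 (2660 unadjusted). All 39 G2/M and mitosis genes were positive (camera adjusted p = 1.1e-07, adjusted p = 0.83 with an estimated correlation) and 27 of 28 immediate early genes negative (adjusted p = 1.5e-10, adjusted p = 0.83 with an estimated correlation). In both lists 0 members passed, also when adjusted over the list alone. These tallies are over all genes, where the median log2 difference of genes with at least 8 CPM was -0.37. Camera called 3 lists up and 18 down over all genes, and 5 up and 11 down over the well expressed ones. Both lists had opposite signs on the 2 dates of P20, as given above, so their signs here depend on how the dates were joined. Without the P20 libraries 3 and 4, 26 genes passed, 2 higher and 24 lower. Mki67 was then at -4.17 ± 0.77 (edgeR adjusted p = 0.014), so its positive sign rested on those libraries.

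Age was compared within each labelled genotype, to ask what changes in these cells from P18 to P20. Each age had its own processing dates, so age and date cannot be told apart. In the libraries labelled WT, the share of counts in genes of the mitochondrial genome was 1.65% to 1.97% at P18 and 0.45% to 0.54% at P20. Over the well expressed genes, 9 of 13 mitochondrial mRNAs fell, 11 when adjusted over the list alone (camera adjusted p = 8.6e-31, adjusted p = 0.0016 with an estimated correlation). Over all genes none of the 13 passed and 11 were lower when adjusted over the list alone (adjusted p = 1.5e-11, adjusted p = 0.31 with an estimated correlation). There mt-Nd6 was at -1.73 ± 0.34 (adjusted p = 0.15, 4 against 3 libraries). The other leading genes did not pass either, among them the polymerase subunit gene Polr1c (1.96 ± 0.36, adjusted p = 0.15), the stress-induced Sesn2 (2.21 ± 0.44), Fdps of cholesterol synthesis (2.40 ± 0.48), and Atg101 of autophagy (1.88 ± 0.38). The carbonic anhydrase gene Car12 (-2.25 ± 0.38), Creb5 (-2.29 ± 0.48) and Ctrc (-2.28 ± 0.49) were negative. Irx5 was at -0.41 ± 0.70, Mki67 at 2.86 ± 1.83 and Gli1 at 1.49 ± 0.66. Fgf18, Brca1, Cd34, Nfatc1 and Lgr5 were at 1.2 ± 1.13, 0.88 ± 1.61, 0.54 ± 0.50, 0.91 ± 0.42 and 0.37 ± 0.42, and Cdkn1a, Irx3 and Irx6 at 1.27 ± 0.68, 0.78 ± 0.38 and -2.15 ± 2.08.

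Of 35 cytosolic ribosomal protein genes, 34 were positive over the well expressed genes, with 1 that rose and 21 when adjusted over the list alone (adjusted p = 7.1e-16, adjusted p = 0.48 with an estimated correlation). Of 15 heat shock and chaperone genes all were positive and 2 rose, 7 when adjusted over the list alone (adjusted p = 1.7e-08, adjusted p = 0.39 with an estimated correlation). In the test over all genes, Hspa8 and Bag3 were at 2.20 ± 0.52 and 1.98 ± 0.44. In Myc-driven ribosome biogenesis 1 of 25 rose, 12 when adjusted over the list alone (adjusted p = 4.5e-07, adjusted p = 0.093 with an estimated correlation). All 12 interferon response genes were negative, with 0 that passed and 1 when adjusted over the list alone (adjusted p = 1.8e-04, adjusted p = 0.39 with an estimated correlation). For age in WT edgeR called 0 of 24592 genes, with 2499 at an unadjusted p under 0.05. It called 66 of 12624 well expressed genes, 36 higher and 30 lower at P20. DESeq2 called 682 and voom with sample quality weights 16157. The count of 0 became 220, 134, 29 and 10 without the libraries labelled P18 WT 3, P20 WT 2, P18 Irx5KO 2 and P18 WT 2. It became 105 without the P20 libraries 3 and 4, and 2 without the 3 libraries richest in receptor genes.

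In the libraries labelled Irx5KO, the share of genes higher or lower at P20 depended on the genes tested and the scaling, as given below. Timp1, an inhibitor of matrix proteases, was at -8.79 ± 1.16 (edgeR adjusted p = 0.0033, 4 against 3 libraries) and the fibrinogen gene Fgg at -6.97 ± 1.35 (adjusted p = 0.018). Summed over the libraries labelled Irx5KO, Timp1 had 4 counts at P20 and 2838 at P18, and Fgg 11 and 2023. The sizes of these 2 falls therefore rest on few counts at P20. Chil1 was at -5.76 ± 0.98 (adjusted p = 0.0087) and Plscr1, an interferon-induced gene, at -5.30 ± 0.96 (adjusted p = 0.011). Sectm1b, Vgf, Slco2b1 and Tcim were at -5.33 ± 1.18, -4.64 ± 0.96, -3.90 ± 0.84 and -3.80 ± 0.69. On the higher side were the transcription factor gene Mycn (3.90 ± 0.66, adjusted p = 0.0087) and Fdps (2.80 ± 0.49, adjusted p = 0.0087). Higher as well were Wnt7b (2.68 ± 0.52, adjusted p = 0.019) and Dscaml1 (5.79 ± 1.04, adjusted p = 0.030). Cwc22, Hmgn5 and Rangap1 were at 2.36 ± 0.48, 2.30 ± 0.43 and 2.27 ± 0.46. Irx5 (0.62 ± 0.71, adjusted p = 0.82), Mki67 (4.99 ± 2.05, adjusted p = 0.40), Brca1 (2.99 ± 1.77) and Gli1 (2.06 ± 0.68, adjusted p = 0.26) did not pass. At P20 they differed between the libraries 1 and 2 and the libraries 3 and 4 as given above. Nor did Fgf18 (0.14 ± 1.09), Cd34 (-0.08 ± 0.49), Nfatc1 (-0.08 ± 0.41), Lgr5 (-0.46 ± 0.41), Cdkn1a (0.13 ± 0.66), Irx3 (0.24 ± 0.37) and Irx6 (2.46 ± 2.25) pass.

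In all, 101 genes passed for age in Irx5KO, 19 higher and 82 lower at P20, and 2849 had an unadjusted p under 0.05. The mitochondrial share was 1.48% to 1.77% at P18 and 0.46% to 0.80% at P20. Of 13 mitochondrial mRNAs 2 fell, mt-Atp8 (-1.87 ± 0.34, adjusted p = 0.011) and mt-Nd6 (-1.86 ± 0.34, adjusted p = 0.011), and 10 when adjusted over the list alone (camera adjusted p = 1.6e-17, adjusted p = 0.13 with an estimated correlation). Over the well expressed genes 9 of 13 fell, 10 when adjusted over the list alone, and the call held (adjusted p = 0.0039 with an estimated correlation). Of 25 Myc-driven ribosome biogenesis genes none passed over all genes and 13 were higher and 1 lower when adjusted over the list alone (adjusted p = 1.3e-11, adjusted p = 0.32 with an estimated correlation). Of these 25 genes 11 rose over the well expressed genes (adjusted p = 0.021 with an estimated correlation). All 39 G2/M and mitosis genes were positive with 0 passing and 1 when adjusted over the list alone (adjusted p = 1.2e-18, adjusted p = 0.53 with an estimated correlation). Of 40 G1/S and DNA replication genes 2 rose, Mcm7 (1.85 ± 0.40, adjusted p = 0.040) and Cdt1 (1.99 ± 0.44, adjusted p = 0.045), and 13 when adjusted over the list alone (adjusted p = 1.9e-14, adjusted p = 0.53 with an estimated correlation). Both tallies join P20 libraries that differ in cell division. Mki67 was at 15.6, 23.3 and 29.7 CPM in those labelled P18 Irx5KO. At P20 it was at 19.4 and 14.9 CPM in Irx5KO 1 and 2, and at 1352 and 1515 CPM in Irx5KO 3 and 4. The rise of Mki67 with age thus lay in the libraries labelled Irx5KO 3 and 4 only.

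Of 25 interferon response genes 1 fell in the libraries labelled Irx5KO, the viral RNA sensor gene Ddx58 (-1.65 ± 0.36, adjusted p = 0.043), and 7 when adjusted over the list alone (adjusted p = 1.2e-05, adjusted p = 0.33 with an estimated correlation). Of 21 NF-kB and cytokine genes none passed and 5 were lower when adjusted over the list alone (adjusted p = 7.0e-08, adjusted p = 0.32 with an estimated correlation). The cytokine gene Ccl2 was at -3.23 ± 0.73 (adjusted p = 0.083), Cxcl1 at -3.29 ± 0.78 and Il6 at -4.97 ± 1.13 (adjusted p = 0.095). Of 12 TGF-beta response genes 2 fell, among them Bhlhe40 (-1.91 ± 0.42, adjusted p = 0.047). There were also 2 when adjusted over the list alone (adjusted p = 0.0054, adjusted p = 0.66 with an estimated correlation). The count of 101 was 62, 28, 67, 207, 322 and 229 without the libraries labelled P18 Irx5KO 1, P18 Irx5KO 3, P20 Irx5KO 3, P18 WT 2, P18 WT 3 and P20 WT 2, and 217 with the replicate number as a block. Without the P20 libraries 3 and 4 it was 284, 87 higher and 197 lower, without the 3 libraries richest in receptor genes 337, with DESeq2 1390 and with voom and sample quality weights 1004. With RLE scaling 363 genes passed, 144 higher and 219 lower, and over the well expressed genes 514, 233 higher and 281 lower.

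**Figure D4:**
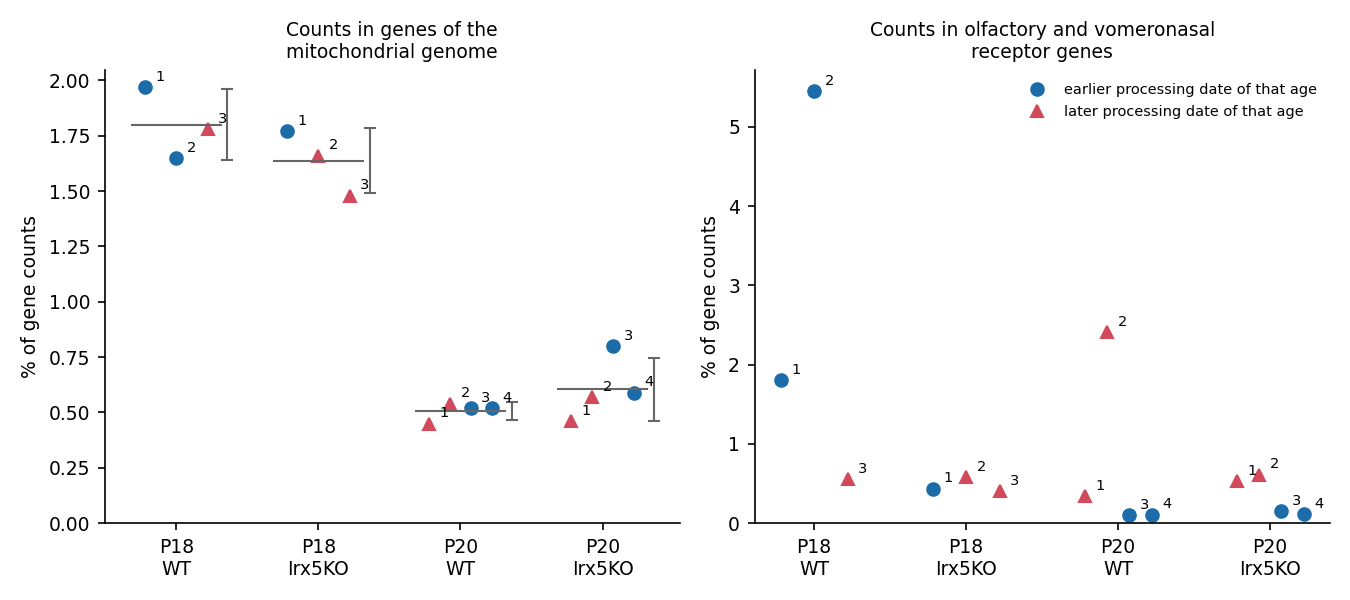
Percent of gene counts in genes of the mitochondrial genome (left, with mean and SD) and in olfactory and vomeronasal receptor genes (right) in each library, by labelled group, with the replicate number beside each point and shapes for the processing date. Mitochondrial shares lie at 1.48% to 1.97% at P18 and 0.45% to 0.80% at P20, and receptor gene shares above 1% are in the libraries labelled P18 WT 1, P18 WT 2 and P20 WT 2.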

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

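Chosen only after the result was seen were the tests of exchanged labels, of Irx5 following cell division, of the WT genotype and of the processing date, and the counts over other splits of the samples, while the 2 tests of genomic DNA were written down beforehand. Of 34 pairs of a group and a measure looked at, 2 had 1 library far from the rest, where chance alone marks about 1 in 20, or 1.7 here.

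Irx5 ran against the genotype labels in the P20 libraries 3 and 4. The mitosis genes there ran opposite to those of the libraries 1 and 2, although the labels alone set no direction for them. The labelled genotype difference of 965 genes differed between the P20 dates, which set this result apart. Genomic DNA counted at Irx5 is argued against, since the background over the length of Irx5 was at most 0.639 CPM in the libraries labelled Irx5KO 3 and 4, where Irx5 had 197 and 175 CPM at raw library sizes. An exchange of genotype labels among these 4 libraries stays open, as those labelled WT 3 and 4, at 39.0 and 43.0 CPM of Irx5, were out of place too, but the r of -0.489 across genes between the dates decides nothing, since it restates the opposite directions and a real reversal would give it as well. That Irx5 follows cell division and not genotype stays open too: the lowest Irx5 of the P18 libraries labelled WT, which had little Mki67, was 1.49 times the highest of those labelled P20 WT 3 and 4, or 2.74 at raw library sizes and 2.37 with TMM over well expressed genes, so 2 of 3 scalings passed the bound of 1.5 set against it, across libraries that differ in age. A real difference between litters, days or sexes in when the cells of each genotype began to divide stays open, although the male libraries labelled Irx5KO 2 and WT 2 (14.9 and 180 CPM of Mki67) ran the other way from the male libraries 3 and 4.

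Receptor gene counts were raised in 3 libraries labelled WT, and the library labelled P20 WT 2, at 24090 CPM, lay far from the 1021 to 3402 CPM of the other P20 libraries labelled WT. The WT genotype alone is argued against, since the lowest library labelled WT had 0.167 times the receptor gene CPM of the highest labelled Irx5KO. Genomic DNA predicts that genes silent in the other libraries follow gene copies. The library rich in Ddx3y (P20 WT 2) was read as male from that gene alone. It should then have a lower ratio of X-linked to autosomal counts than the 2 with little Ddx3y (P18 WT 1 and 2). The ratio of these ratios was 0.259 (95% bootstrap interval 0.182 to 0.329), below the range set for genomic DNA and below that set against it, and 0.578 when means replaced medians, a check added later. Genomic DNA and other sources of low counts over silent genes therefore cannot be told apart here, because the value depends on how it is averaged.

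Mitochondrial mRNAs took a smaller share of counts at P20 in both labelled genotypes, with age means of 1.72% and 0.556%, a ratio of 3.09. The processing date cannot be told apart from age, because no date held both ages. Between the 2 dates of an age the mean share differed by at most 1.2 times, between the bounds set for and against the date. The single gene mt-Nd3, chosen after its values were seen, was at 0 CPM in all P20 libraries, but also at 0 and 0.566 CPM in those labelled P18 WT 1 and 2, against 12.9 to 62.2 CPM in the other P18 libraries, so its estimate did not part the ages alone. Age itself stays open as an untested explanation.

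In the same library labelled P20 WT 2, Irx6, the third gene of the Irx3 and Irx5 cluster, was at 2.15 CPM and at 0 in the other 3 P20 libraries labelled WT. At raw library sizes its 2.98 CPM lay below the 9.84 CPM that the receptor gene level of that library gives over the length of Irx6, and P20 Irx5KO 1 and 2 had 1.07 and 0.622 CPM, so the value does not stand out. Transcripts matched to no gene, which the comparisons did not use, held 2.24% and 2.59% of counts in the libraries labelled P20 Irx5KO 3 and 4, above the highest value of 2.10% among the P20 libraries labelled WT.

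Other splits of the samples were fitted for each comparison. At P18 the 10 possible splits are too few for a share under 0.05; 9 could be fitted, with 0 genes in the real one and at most 1 in another. At P20, for the difference between ages and for age in WT the real split called 0 genes, a count that any split reaches, so these counts say nothing about chance. At P20 all 34 fitted splits reached it, and the highest, 618, set Irx5KO 1, Irx5KO 2, WT 3 and WT 4 against the other 4, which points to a structure of the samples, and the values within each date are those in the report. For the difference between ages, 76 of 80 drawn splits could be fitted, all 76 reached 0, and the highest called 72. For age in WT all 35 splits did, and the highest, 4088, set P18 WT 1, P18 WT 2 and P20 WT 2, the 3 libraries richest in receptor genes, against the rest, again a structure of the samples. For age in Irx5KO the real split called 101 genes and 1 of 35 splits, the real one, reached that count, the highest other being 1. This argues against an arbitrary division of these libraries as the source of the count. The share is the smallest that 35 splits can give, so chance is not excluded, and neither is the date.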

How the results depend on the processing

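Chosen only after the result was seen were the tests over well expressed genes, those without the P20 libraries 3 and 4 or without the 3 libraries richest in receptor genes, and every alternative to the fits within a date. Where a count moved, the cause was not tested, except that fits without libraries hold fewer samples and those over well expressed genes test fewer genes. No setting varied the depth, so what depth limits was not measured. Without a filter more genes were called in every comparison, and in data simulated at the real depths with 4-fold changes between 4% and 52% were recovered across the comparisons of all libraries. Among the values of single named genes under other settings, 850 of 891 at P18, 736 of 838 at P20, 638 of 781 for age in WT and 868 of 1073 for age in Irx5KO had the same direction and side of the threshold. The main test called 0 genes at P18, at P20 and for age in WT, so there the side could change only by a new call. Within the P20 libraries 1 and 2, 878 of 1055 were the same and 131 lost their call. Within the libraries 3 and 4 these were 1025 of 1097 and 50.

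Counts of genes called at P18, P20, for the difference between ages, age in WT and age in Irx5KO were 0, 0, 0, 0 and 101. They were 117, 226, 21, 66 and 305 without a filter and 19, 85, 13, 682 and 1390 with DESeq2. With voom and sample quality weights, P18, P20, age in WT and age in Irx5KO gave 11, 135, 16157 and 1004. Age in WT gave 40 with RLE scaling and 1 with length offsets. Age in Irx5KO gave 363 with RLE scaling, 162 with the stricter filter, 155 with only the Irx5KO libraries and 63 with the date as a random effect. Over well expressed genes, age gave 66 in WT and 514 in Irx5KO. Without the P20 libraries 3 and 4, P20 gave 119, the difference between ages 26, and age 105 in WT and 284 in Irx5KO, or 233 and 705 over well expressed genes. Without the 3 receptor-rich libraries, age gave 2 in WT and 337 in Irx5KO. Each P18 date had a single library on 1 side. The P20 libraries 1 and 2 gave 116 genes and the libraries 3 and 4 gave 1028. These are the differences within a date from the fit of all libraries, not fits of those libraries alone.

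With the replicate number as a block, P20 gave 1 gene and age in Irx5KO 217, and the block moved no other count of genes called by over 1.5 times. At P18 it called no gene, but more genes had an unadjusted p under 0.05 than without it. At P20 the numbers share no more than a number, since the correlations of same-numbered libraries were 0.0333, 0.389, 0.132 and 0.272 and not every library correlated best with its own number.

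Within a date, the counts for the earlier P18 date, the P20 libraries 1 and 2, the P20 libraries 3 and 4 and the difference of the P20 dates were 795, 665, 2109 and 2021 without a filter and 363, 463, 2647 and 2404 with DESeq2. With voom and sample quality weights the first 3 were 0, 11 and 1937. Without the 3 receptor-rich libraries the last 3 were 209, 1863 and 1516. The single gene of the later P18 date became 0 with RLE scaling, the stricter filter, voom, length offsets or well expressed genes, and 26, 3 and 4 without a filter, with DESeq2 and without the receptor-rich libraries.

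Lists called at P18, P20, for the difference between ages, age in WT, age in Irx5KO, and within the P20 libraries 1 and 2 and 3 and 4 were 28, 15, 21, 32, 22, 23 and 20. With an estimated correlation they were 0, 0, 0, 0, 0, 3 and 3, and over well expressed genes as well 0, 0, 0, 1, 2, 2 and 2. Fry, a test of direction that sets no list against other genes, called 0, 0, 0, 2, 5, 3 and 10, and 9 for the difference of the P20 dates. Over well expressed genes with the preset correlation, P18, P20 and age in WT gave 16, 7 and 14.

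Reversed values were these. The log2 Irx5 difference at P20 was -2.00 without the libraries 3 and 4 (exact permutation test, p = 0.333, the smallest possible). In the gene test at P20 it was -2.00 within libraries 1 and 2. Brca1 was at -3.97 without libraries 3 and 4 and within 1 and 2, Mki67 at -4.31 and -4.32, and Gli1 at 1.90 within 3 and 4. For the difference between ages, Mki67 was at -4.17 without libraries 3 and 4. For age, Brca1 in WT was at -2.83 with voom and sample quality weights, and Irx5 in Irx5KO at -1.40 over well expressed genes without libraries 3 and 4.

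Leaving out 1 library in turn, where a lone library left in a cell is assumed to vary like the others, counts ranged from 0 to 1 at P18 (1 without P18 WT 3), 0 to 0 at P20, 0 to 1 for the difference between ages (1 without P18 WT 3), 0 to 220 for age in WT and 28 to 322 for age in Irx5KO. Within dates they ranged from 1 to 1160 on the earlier P18 date (1160 without P18 WT 1), 0 to 20 on the later one (20 without P18 WT 1), 15 to 393 and 415 to 1845 within the P20 libraries 1 and 2 and 3 and 4, and 510 to 1742 for their difference. Lists ranged from 8 to 34, 11 to 22, 5 to 26, 29 to 38, 19 to 28, 15 to 31 and 13 to 24 in the order above. At P18, 8 lists were left without Irx5KO 1. For the difference between ages 5 and 10 were left without P18 Irx5KO 1 and P18 WT 2. The log2 ratio of mean Irx5 ranged from -0.64 to -0.06 at P18 and 0.13 to 1.04 at P20.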

Other observations

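Signals of stem cell quiescence and of the bulge were also measured within the P20 libraries 3 and 4, by the labelled genotype. Of 21 quiescence factors 2 fell in the libraries labelled Irx5KO, Fgf18 (-4.04 ± 0.73) and Cdkn1c (-2.99 ± 0.44), and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.022, adjusted p = 0.92 with an estimated correlation). Of 12 FGF ligand and receptor genes 3 fell, while over the list alone 3 fell and 1 rose (adjusted p = 0.0035, adjusted p = 0.11 with an estimated correlation). The bulge markers Angptl7 and Postn were at -4.10 ± 0.62 and -2.00 ± 0.55 (adjusted p = 0.043). The integrin gene Itgb6, a bulge marker of the same list, went the other way at 2.41 ± 0.42 (adjusted p = 0.0014). Of 9 inner bulge and companion layer markers 2 fell, 4 when adjusted over the list alone (adjusted p = 0.0027, adjusted p = 0.49 with an estimated correlation). Of 17 mismatch repair genes 3 rose, among them the ligase gene Lig1 (2.10 ± 0.39), and 4 when adjusted over the list alone (adjusted p = 2.9e-07, adjusted p = 0.11 with an estimated correlation). Of 19 base excision repair genes 3 rose, also 3 when adjusted over the list alone (adjusted p = 0.0024, adjusted p = 0.11 with an estimated correlation). Both repair lists share members with the G1/S list, such as Pcna and Fen1, and a change apart from cell division was not tested.

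For age in the libraries labelled Irx5KO, camera also called the 3 lists below, in which 0 members passed and which were not called with an estimated correlation. Of 15 granular and cornified epidermis markers, 13 were positive with 0 passing (camera adjusted p = 6.6e-06, adjusted p = 0.53 with an estimated correlation). Of 11 infundibulum and junctional zone markers 9 were negative, with 0 passing and 3 lower when adjusted over the list alone (adjusted p = 8.0e-04, adjusted p = 0.61 with an estimated correlation). Of 12 class I antigen presentation genes 11 were negative, with 0 passing and 2 lower when adjusted over the list alone (adjusted p = 1.4e-04, adjusted p = 0.53 with an estimated correlation).

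The log2 differences of the earlier P18 date and of the P20 libraries 1 and 2 had a Pearson r of 0.376 and a Spearman rho of 0.371 across 10356 genes, which are not independent replicates, and 63.1% had the same sign. The earlier and later P18 dates had an r of 0.117. The libraries richest in receptor gene counts, P18 WT 1, P18 WT 2 and P20 WT 2, all enter the first of these pairs on the WT side. On the earlier P18 date the kinetochore gene Kntc1 was at -3.29 ± 0.68 (adjusted p = 0.46), Irx5 at -0.43 ± 0.50 and Mki67 at -0.74 ± 0.66. On the later one Irx5 was at -0.82 ± 0.48 and the neurotrophin receptor gene Ngfr at 2.68 ± 0.67, and none of these genes passed.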
